A study of Rattus norvegicus with 2 samples.

How the data were processed

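Expression data were taken from 1 control array and 1 5ppase array of rat astrocytes, each sample grouped by its title in the labels. Per the labels' protocols, RNA was extracted with RNeasy and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. The deposited values are single-colour intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. In the deposited values both arrays have a trimmed mean of 500.2 with 2% removed at each end, as global scaling by the authors to one target would give. Such scaling sets 1 factor per array, so it leaves any signal-dependent trend between arrays in place, and no detection calls were used here. No sample column was left unused (0).

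Probe sets were named through a platform annotation table, which can be old, and current symbols were looked up by gene identifier in a rat RefSeq gene table (GRCr8), used for names and synonyms and not for coordinates, since no genome build is named for the values. Of 31099 probe sets 20832 carried 1 gene symbol, 436 carried several and 9831 were not listed in the table. Of those with 1 symbol, 20764 matched a current entry and 0 symbols changed. Probe sets with several symbols or none were given no gene name. A gene was represented by its probe set with the highest mean signal, which gave 14218 genes. Other probe sets of a gene can read other transcript ends or splice forms and can disagree with it.

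The arrays were scaled to a common trimmed mean, which moved neither array by more than rounding. Signals under a floor, the 40th percentile of both arrays pooled (62.0), were raised to it before log2. The floor is a percentile of the data and not a detection call. On the control array 59.5% of probe sets and on the 5ppase array 60.4% lay above it. A gene was compared where it lay above the floor on both arrays and reached the pooled 60th percentile (208) on at least 1, which left 8261 genes, and the ratio of 5ppase to control was taken on the log2 scale. Raising low signals to the floor understates ratios of dim genes. A gene that reached the 60th percentile on 1 array and lay at or under the floor on the other was given only a bound, the bright signal over the floor. With 1 array per group no test was run and no p-value was computed. Spread was described by pairs of probe sets of 1 gene: over 1883 genes with 2 compared probe sets, the SD of the difference of their log2 ratios divided by the square root of 2 was 0.26, which covers probe and hybridisation noise and not differences between cultures. The number of arrays limits the precision of every value.

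There were 28 gene lists, for calcium signalling, calcium-responsive genes, adhesion, matrix, metabolism, stress, cell cycle and the cell types a brain culture can hold, fixed before the data were examined. Of their 999 distinct symbols, some of them in several lists, 873 were found on the array, 21 by synonym. Members with a mean signal above the floor counted as measured, among 10255 such genes. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched in 20 bins of signal, and lists under the 2.5th or over the 97.5th percentile were said to lie outside the range of random lists. At least 5 measured members were needed, so the microglial list was not scored. Genes of a list are correlated and some belong to several lists, so this percentile describes these arrays and is not a test.

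Genes were named by a rule fixed before the data were examined: the 12 largest log2 ratios each way among compared genes, without loci that have only a provisional symbol; up to 4 members per list at least 2-fold apart or, if none was, the 2 brightest; the 5 brightest genes above the floor on 1 array only, each way; and Inpp5a, Itpr1, Itpr2, Itpr3, Gfap, Cdh2, Fos, Gapdh and Actb whatever their values. Actb had no probe set with a single gene symbol, and control probe sets of beta-actin stand in for it. Other genes are marked where they were chosen after their values were seen.

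The alternatives fixed before the data were examined were the values as deposited, a common median, quantile normalization, removal of a loess trend (span 0.3), floors at the 25th and 60th percentiles (the latter with the 75th for the brighter array), a pseudocount of the 10th percentile (6.4) with no floor or filter, the mean of a gene's probe sets, only probe sets without the _x_at or _s_at suffix, the second brightest probe set and a 3-fold threshold. List medians without members above the floor on 1 array only, and over members compared on both arrays, were added after the data were seen. The procedure was tested on data simulated for 5ppase against control with all 14218 genes, with noise of the size of the probe set spread. It recovered 98 of 100 genes changed by a log2 ratio of 1.5 and 100 of 100 changed by 3.0, called 1 of 5715 unchanged genes 2-fold apart, placed 7 of 200 unchanged lists (3.5%) outside the range of random lists and placed 20 of 20 lists shifted by 0.3 there. These simulations hold no variation between cultures. Changed genes were drawn only from genes with a mean signal far above the 60th percentile, and noise had the same size at every signal. Recovery of dim genes, and noise that grows at low signal, were therefore not tested. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.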

Results

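Gene expression was measured in astrocytes, the main supporting glial cells of the brain, cultured from the hippocampus of embryonic day 18 Sprague-Dawley rats. The control culture expressed a red fluorescent protein alone, and the 5ppase culture expressed 5ppase together with that protein from a bicistronic vector. Total RNA from each culture was hybridised to a single-colour Affymetrix rat array, 1 array per group, with 31099 probe sets on each. The series compares astrocytes with active calcium signalling (control) with astrocytes in which this signalling is absent (5ppase), so the comparison asks which transcripts differ between these states. The labels do not spell out 5ppase; the name commonly stands for an inositol phosphate 5-phosphatase, an enzyme that inactivates inositol trisphosphate, the messenger that releases calcium from the endoplasmic reticulum. Signals ran from 0.1 to 43892 with a median of 107 on the control array and from 0.2 to 49734 with a median of 109 on the 5ppase array. There were no replicates, so the differences below describe these 2 arrays, have no replicate check and carry no p-value, and the number of arrays limits their precision.

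Inpp5a, the rat gene of the type I inositol phosphate 5-phosphatase, gave 994 on the control array and 1023 on the 5ppase array at its brightest probe set (log2 ratio 0.04, here and below 5ppase over control). Its second probe set gave 10.4 and 133.6. The labels name neither the phosphatase gene of the construct nor its species, and no source used here says which part of the message these probe sets read, so neither value checks the labels. The 5′ and 3′ probe sets of control genes, which report RNA integrity, had log2 ratios that differed by 0.13 for beta-actin, 0.066 for GAPDH and 0.0064 for hexokinase.

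The ratios in this paragraph were ranked among named genes above the signal floor on both arrays and bright on at least 1, without provisional loci. The largest towards the control array was that of Mgp, a secreted inhibitor of calcification, at 1902 in control and 199 in 5ppase (log2 ratio -3.26). It was followed by Col18a1, a basement membrane collagen (-2.78), the matrix protease Mmp3 (-2.28), the junctional adhesion molecule Jam2 (-2.27) and Scg2, a secretory granule protein (-2.23). The other 7 of the 12 largest ratios towards control belonged to the Frizzled ligand Ndp (-2.09), Plekhb1 (-2.07), the growth factor binding protein Igfbp5 (-2.06), the peptide transporter Slc15a2 (-2.03), the brain fatty acid binding protein Fabp7 (-2.01), the serotonin receptor Htr5b (-1.98) and Lsr, a lipoprotein receptor of cell junctions (-1.93). Towards 5ppase the largest ratio among these genes was that of the caveolar protein Cavin2, at 137 in control and 804 in 5ppase (2.56). T-cadherin (Cdh13, 2.25), a DNA polymerase alpha subunit (Pola2, 2.19), the tenascin Tnn (2.13), the mitotic cyclin Ccnb1 (2.13), Arhgap24 (1.91), the annexin Anxa3 (1.91) and the cysteine dioxygenase Cdo1 (1.86) followed. Olfm1 (1.79), the vasopressin receptor Avpr1a (1.74), the neuronal tubulin Tubb3 (1.72) and the transporter Slc4a11 (1.70) completed the 12.

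Of the 8261 genes above the floor signal of 62.0 on both arrays and bright on at least 1, 124 were at least 2-fold higher and 117 at least 2-fold lower in 5ppase, 2.92% together. The median log2 ratio was -0.017, and 7376 genes (89.3%) lay within 1.5-fold. Across genes the arrays correlated with a Pearson r of 0.968 on log2 signals and a Spearman coefficient of 0.965; genes are not independent replicates. A second probe set was the only internal repeat. Of the 42 genes whose brightest probe set was at least 2-fold apart and that had a second one compared on both arrays, all 42 second probe sets pointed the same way, 36 of them by at least 1.5-fold, and among the other 1841 genes 1195 (64.9%) did. Second probe sets of Col18a1 (-1.49), Jam2 (-1.56), Ndp (-2.08), Igfbp5 (-1.97), Cdh13 (3.36), Ccnb1 (1.30) and Olfm1 (1.58) had the sign of the first. With the floor at the 60th percentile of signal and the brighter array required to reach the 75th, 66 genes were higher and 56 lower, and with a pseudocount in place of floor and filter 1111 and 976. The floor alone at the 25th percentile gave 134 and 120.

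**Figure D1:**
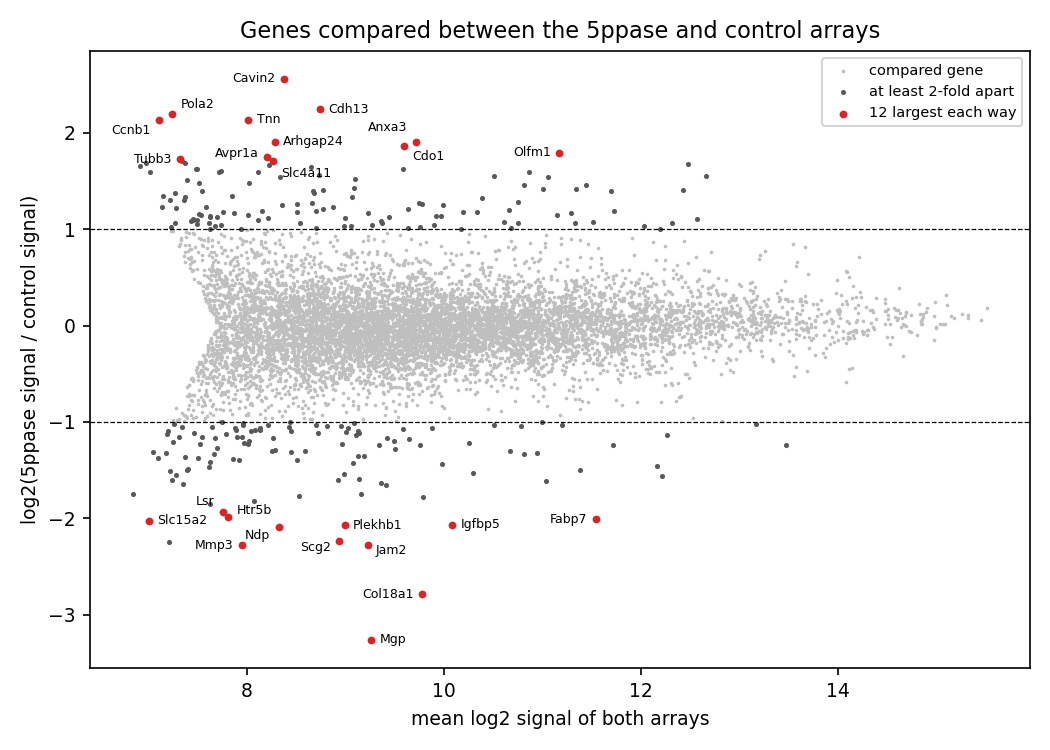
Each point is 1 of the 8261 genes compared on both arrays, with its mean log2 signal on the horizontal axis and its log2 ratio of 5ppase over control on the vertical axis; dashed lines mark 2-fold, dark points lie beyond them, and red points with symbols are the 12 named genes with the largest ratio each way. Among genes without a provisional symbol Mgp lies lowest at -3.26 and Cavin2 highest at 2.56, while most genes lie near 0 at every signal.

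Some genes were bright on 1 array and at or under the floor on the other, 12 in 5ppase only and 6 in control only. The brightest in 5ppase only were the aldo-keto reductase Akr1c15 (657, at least 10.6-fold higher), placental growth factor Pgf (512, at least 8.25-fold), the lipid raft protein Rftn1 (415, at least 6.70-fold), the uridine phosphorylase Upp1 (385, at least 6.2-fold) and the water channel Aqp1 (359, at least 5.79-fold). The brightest in control only were Cldn11, a tight junction claudin (1371, at least 22.1-fold lower in 5ppase), the astrocyte water channel Aqp4 (432, at least 6.97-fold), Dpysl5 (286, at least 4.61-fold), Bex1 (249, at least 4.01-fold) and Tmem229b (231, at least 3.73-fold). Each bound is the bright signal over the floor. Second probe sets gave 72.1 in control and 446.5 in 5ppase for Pgf but 154 and 193 for Aqp1. They gave 78.0 and 22.2 for Cldn11. For Aqp4 (14.3 and 32.6) and Rftn1 (7.6 and 16.5) they were under the floor on both arrays. With the floor at the 25th percentile the counts were 2 in 5ppase only and 3 in control only.

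Astrocyte markers were lower in the 5ppase array. Gfap, the intermediate filament protein of astrocytes, gave 17525 in control and 7408 in 5ppase (log2 ratio -1.24), and Fabp7 gave 5972 and 1486. Mlc1, a membrane protein of perivascular end feet, gave 2551 and 1037 (-1.30), the sodium pump subunit Atp1b2 gave 1088 and 476 (-1.19), and Aqp4 was at 432 and 25.1. The second probe sets of Atp1b2 and Aqp4 were under the floor on both arrays. Of the 18 measured markers 13 had a negative ratio and 5 a positive one: Slc4a4 (0.65), Id4 (0.20), Cst3 (0.073), Gja1 (0.072) and S100b (0.05), named after their values were seen; Cst3 turned negative under quantile normalization and after loess and Gja1 under quantile normalization. The list median was -0.53, below the medians of all 10000 random gene lists of the same size and signal, a description of these arrays. With second brightest probe sets, which 7 of these genes have above the signal floor, the median was -0.13 at the 18.4th percentile, inside the range of random lists. The brightest probe sets of the same 7 genes had a median of only -0.20, that of Clu. The smaller median thus mostly reflects which genes have a second probe set, but single genes moved. Second probe sets gave 1.04 for Gja1, 0.95 for Slc4a4 and 0.59 for Id4, all further up than the first. They gave -0.52 for Glul, -0.51 for Fgfr3, -0.22 for Clu and -0.13 for Slc1a3.

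**Figure D2:**
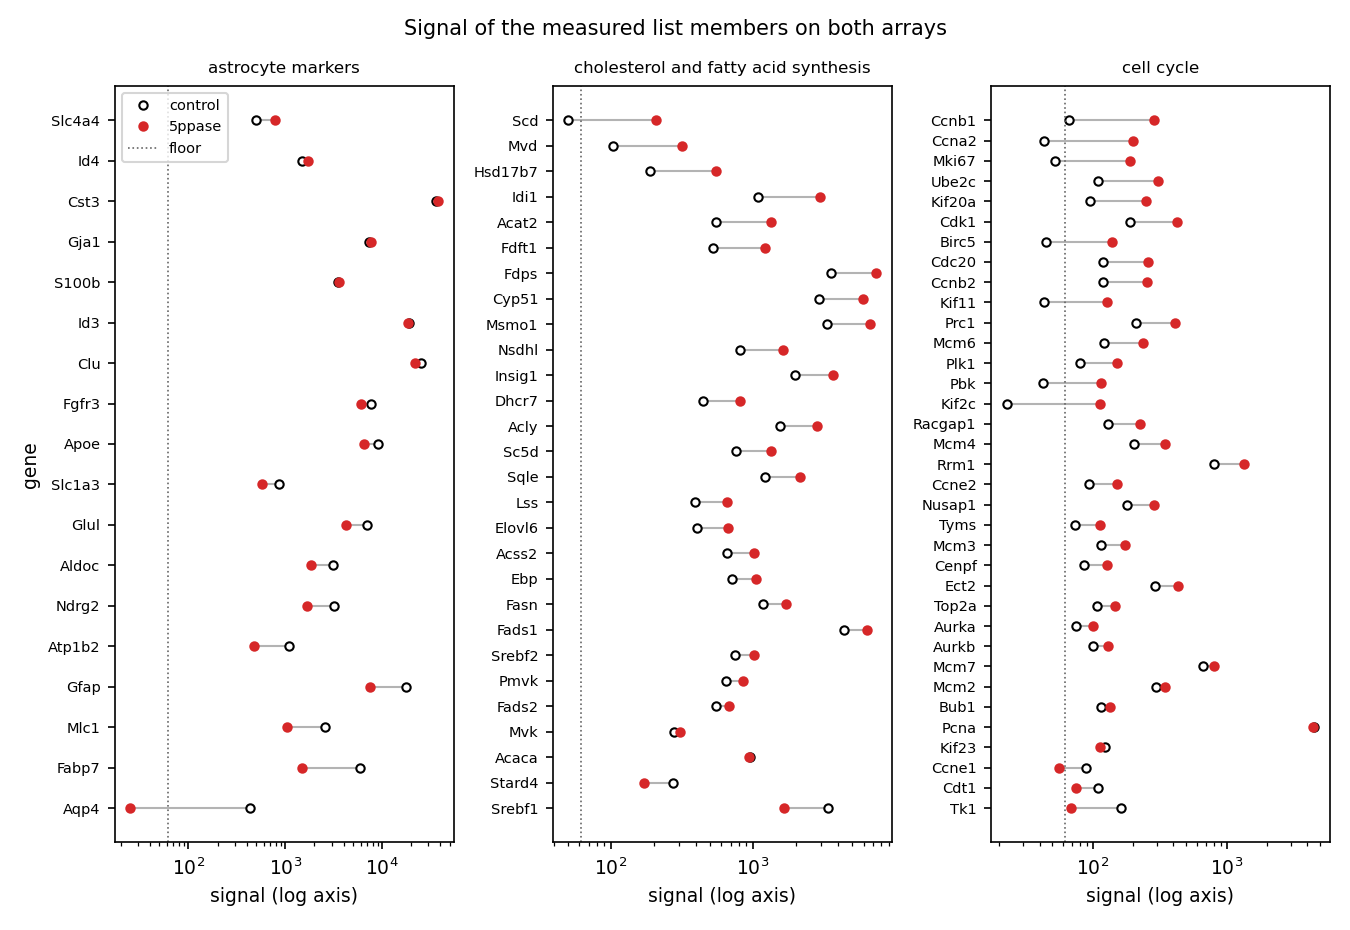
Signals of the measured members of the astrocyte, cholesterol and fatty acid synthesis, and cell cycle lists on a log axis, 1 line per gene, with the control array as open circles, the 5ppase array as red circles and the floor of 62.0 as a dotted line. Most astrocyte markers lie lower in 5ppase, as Gfap does at 17525 and 7408, and most members of the other lists lie higher, cell cycle genes close to the floor.

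Markers of other cell types differed in both directions. Fibroblast and meningeal markers had a median of -0.15 at the 0.19th percentile of matched random lists, with 16 members lower and 9 higher, led by Mgp and Igfbp5; the mean was -0.36, and with the floor at the 25th percentile (-0.063) or with second probe sets (-0.083) the median lay inside the range of random lists. The fibrillar collagens were bright on both arrays, Col1a1 at 32792 and 32414 and Col3a1 at 25144 and 27757, as chosen after their values were seen. Among neuron markers, Tubb3 (87.9 and 290) and the tubulin regulator Stmn2 (3766 and 11065, 1.55) were higher in 5ppase. The Tubb3 value comes from a probe set of the _s_at kind, and its other probe set was under the floor on both arrays (20.1 and 47.7). The GABA synthesis enzyme Gad1 (998 and 422, -1.24) was lower. Of 17 measured members 8 were higher and 9 lower, with a median of -0.021 and a mean of 0.17. That median was 0.015 with common median scaling, 0.22 at the 96.0th percentile over the 22 members left by a floor at the 25th percentile and 0.20 at the 94.0th over 32 with the pseudocount, but -0.19 over the 6 left by the 60th percentile floor. The oligodendrocyte lineage list had only 7 measured members, with a median of -0.37 at the 2.79th percentile; Cldn11 was lower and the progenitor proteoglycan Cspg4 higher (262 and 630, 1.27). With a common median, quantile normalization or the loess trend removed, this list lay under the 2.5th percentile, but its median was -0.24 at the 7.12th over the 16 members left by a floor at the 25th percentile and -0.068 at the 31.4th over 23 with a pseudocount and no floor. Among endothelial and pericyte markers, Ocln, an integral tight junction protein, was lower (1212 and 384, -1.66) and Cspg4, also listed there, was higher (1.27). The median of this list was 0.011 over 12 members. Its median was 0.32 at the 97.3rd percentile with the floor at the 25th percentile (17 members), 0.31 at the 95.9th with the pseudocount (28 members) and 0.21 with the mean of probe sets or without those of the _x_at and _s_at kinds. It was -0.15 with the 60th percentile floor and -0.48 at the 2.08th with second probe sets (5 members each). The 5 measured ependymal markers had a median of -0.34 at the 10.4th percentile, with Tekt1 at -0.29 and Rfx3 at -0.49. Only 1 of the 5, Tekt1, was bright enough to be compared on both arrays. Rfx3 gave 156 and 111. Only 3 of 30 microglial genes on the array were measured, too few to score: Tmem119 at 1078 and 2273 (1.08) and, chosen after their values were seen, Csf1r at 68.8 and 77.5 and Aif1 at 56.1 and 71.5.

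Genes of cholesterol and fatty acid synthesis were higher in the 5ppase array. Mvd, an enzyme of the mevalonate pathway, gave 103 in control and 318 in 5ppase (log2 ratio 1.63), and the sterol enzyme Hsd17b7 gave 189 and 550 (1.54). The isoprenoid enzyme Idi1 gave 1085 and 2984 (1.46) and the acetyl-CoA acetyltransferase Acat2 gave 552 and 1335 (1.27). Of 28 measured genes 25 had a positive ratio, 9 of them at least 2-fold, and the desaturase Scd, chosen after its values were seen, was above the floor in 5ppase only. The 3 with a negative ratio, named after their values were seen, were the transcription factor Srebf1 (3366 and 1642, -1.04), Stard4 (-0.69) and Acaca (-0.017), the last positive under each other scaling. The list median was 0.82, above the medians of all 10000 matched random lists. Second probe sets, available for 12 of the genes, had a median of 0.45 at the 99.95th percentile.

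Cell cycle genes were also higher in the 5ppase array. Ccnb1, the cyclin that drives entry into mitosis, gave 65.9 and 288, its kinase Cdk1 gave 188 and 428 (log2 ratio 1.18), the mitotic ubiquitin-conjugating enzyme Ube2c gave 109 and 305 (1.48) and the kinesin Kif20a gave 96.0 and 249 (1.37). Of 35 measured genes 30 had a positive ratio and 5 a negative one, namely Tk1 (-1.25), Cdt1 (-0.56), Ccne1 (-0.53), Kif23 (-0.12) and Pcna (-0.044), named after their values were seen. The list median was 0.75, above the medians of all 10000 matched random lists. Most of these signals were low, with a median over the members of 110 in control and 189 in 5ppase. Only 16 members were above the floor on both arrays and bright on at least 1. Of these, 12 were at least 1.5-fold higher and none that much lower. The filter shapes this split, since a member dim in control passes only where its 5ppase signal is bright. Tk1 was not among the 16.

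Genes of the actin cytoskeleton and smooth muscle were mostly higher in 5ppase. Smooth muscle myosin Myh11 gave 857 and 1937 (log2 ratio 1.18), the regulatory light chain Myl9 gave 9813 and 17259 (0.81), tropomyosin Tpm2 gave 14770 and 24261 (0.72) and smooth muscle actin Acta2 gave 14268 and 21070 (0.56), the last 3 named after their values were seen. Of 30 measured genes 25 had a positive ratio and 5 a negative one, or 22 and 8 under quantile normalization. The list median was 0.32, above the medians of all 10000 matched random lists. The second probe set of Myh11 was under the floor on both arrays.

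Extracellular matrix genes went both ways. Mmp3 gave 545 and 112, Ptprz1, a receptor phosphatase that carries chondroitin sulfate, gave 977 and 323 (log2 ratio -1.60) and the secreted phosphoprotein Spp1 gave 1659 and 614 (-1.43), whereas the collagen chains Col4a1 (0.71) and Col6a2 (0.67), chosen after their values were seen, were higher. Of 48 measured genes 28 were higher and 20 lower; the median of 0.11 lay at the 98.5th percentile of matched random lists, while the mean was -0.022. That position did not hold: the median was 0.064 (95th percentile) under quantile normalization, 0.013 (36.8th) over the 43 members compared on both arrays, an alternative added after the data were seen, and -0.066 with second probe sets.

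Among growth and trophic factors, the growth inhibitory metallothionein Mt3 (8151 and 2768, log2 ratio -1.56) and neurotrophin Ntf3 (408 and 192, -1.09) were lower in 5ppase and the bone morphogenetic protein Bmp6 (1153 and 2325, 1.01) was higher. Of 31 measured genes 17 were higher and 14 lower, with a median of 0.12 at the 97.8th percentile that lay inside the range of random lists under quantile normalization (0.071), after loess (0.061) and with the mean of each gene's probe sets (-0.015). Adhesion genes gave a median of -0.06 at the 20.5th percentile and a mean of 0.10. N-cadherin (Cdh2), a calcium-dependent adhesion molecule, gave 5457 and 4462 (-0.29), with -0.38 at its second probe set, against the 2.25 of Cdh13. Over the 15 adhesion genes compared on both arrays, an alternative added after the data were seen, the median was -0.29 at the 0.06th percentile. With the floor at the 25th percentile it was -0.018 at the 37.3rd, and over 7 second probe sets it was positive, 0.14 at the 83.7th. Guidance molecules had a median of 0.098 at the 91.4th percentile (-0.043 with second probe sets), with 16 of 26 genes higher, and the ephrin receptor Ephb1 was lower (591 and 224, -1.40).

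Of the 29 genes of inositol phosphate and calcium signalling compared on both arrays 25 lay within 1.5-fold, beside 89.3% of all compared genes. The inositol trisphosphate receptors, the calcium release channels of the endoplasmic reticulum, went different ways: Itpr1 gave 1516 and 2300 (log2 ratio 0.60), Itpr3 gave 439 and 298 (-0.56), and Itpr2 gave 79.4 and 117.5 (0.57) but 98.8 and 72.8 at its second probe set. Phospholipase C epsilon (Plce1) was the only member at least 2-fold apart, at 1363 and 651 (-1.07). Of 35 measured genes 20 were higher and 15 lower. The median was 0.08 at the 92.2nd percentile of matched random lists.

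Several immediate early genes, which respond to calcium and other stimuli within minutes, had lower signals in 5ppase. Fos gave 8260 and 4238 (log2 ratio -0.96; a dim second probe set went the other way, 73.4 and 129.3), Fosb gave 326 and 118 (-1.46) and the orphan receptor Nr4a1 gave 622 and 287 (-1.11). Ier2 (-0.78), Junb (-0.77), Egr2 (-0.72), Nr4a3 (-0.69), Jun (-0.67) and Egr1 (-0.61), named after their values were seen, were lower as well. Ptgs2, the inducible prostaglandin synthase (339 and 852, 1.33), and the transcription factor Klf4 (657 and 1565, 1.25) were higher. Of the 26 members compared on both arrays 9 were at least 1.5-fold lower and 2 at least 1.5-fold higher; over all 33 measured, 20 were lower and 13 higher and the median of -0.097 lay at the 8.59th percentile, inside the range of random lists. Over 9 second probe sets the median had the other sign, 0.065 at the 68.7th percentile. Calcineurin-NFAT and CREB targets had a median of -0.16 at the 5.42nd percentile, with 14 of 21 lower. This list also holds NFAT transcription factors themselves. Among its members Scg2 (1063 and 226) and the NFAT factor Nfatc4 (754 and 351, -1.10) were lower. A dimmer second probe set of Nfatc4 gave 155.6 and 126.8 (-0.30). The cytokine Il6 (1194 and 2499, 1.07) and Ptgs2 (1.33), also in this list, were higher. The median of this list was -0.18 at the 2.14th percentile under quantile normalization. It was -0.088 at the 23.3rd with the mean of each gene's probe sets and -0.056 at the 40.5th with the 60th percentile floor.

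Genes linked to reactive astrocytes had a median of 0.10 at the 90.1st percentile, with 17 of 23 members higher. The protease inhibitor Serpina3n was higher (1072 and 3242, log2 ratio 1.60), the sphingosine phosphate receptor S1pr3 lower (7575 and 2770, -1.45), and Gfap lower. Second probe sets of 5 of these genes had a median of 0.55 at the 99.9th percentile. Inflammatory genes had a median of 0.12 (91.5th percentile), with Il6 higher and the NF-kappa B inhibitor Tnfaip3 lower (1129 and 464, -1.28). Interferon response genes had a median of -0.015 (45.6th percentile), positive under each other scaling and 0.081 with the pseudocount, with the protease Usp18 at 238 and 107 (-1.16). The receptor and transporter list had a median of 0.022 (60.3rd percentile), with the lysophosphatidic acid receptor Lpar1 at 89.7 and 292 (1.70). That median was negative under quantile normalization (-0.014) and with the pseudocount (-0.016), the floor at the 25th percentile (-0.17 at the 4.31st, 31 members), the 60th percentile floor (-0.16 at the 7.40th) and second probe sets (-0.30 at the 5.94th).

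Most stress and maintenance genes differed little. Unfolded protein response genes had a median of 0.14 at the 99.5th percentile of matched random lists, with 22 of 30 higher and none 2-fold apart; the transcription factor Atf4 gave 13188 and 15897 (log2 ratio 0.27) and the amino acid transporter subunit Slc3a2 13567 and 12969 (-0.065), and second probe sets of 5 genes had a median of -0.074. Oxidative stress genes had a median of 0.13 at the 97.3rd percentile and reached the 99.5th (0.18) with the mean of each gene's probe sets. The glutathione peroxidase Gpx3 was higher (3185 and 10160, 1.67) and the metallothionein Mt3 lower (-1.56). Hypoxia and glycolysis genes had a median of -0.042 (11.7th percentile; 0.021 with second probe sets), with the collagen prolyl hydroxylase P4ha2 at 2010.2 and 4245 (1.08). All 45 oxidative phosphorylation genes lay within 1.5-fold (median 0.066, 80.8th percentile), Cox4i1 at 0.12 and Cox6c at -0.033, the latter positive with common median scaling. Ribosomal protein genes had a median of 0.017 (8.29th percentile) that was -0.045 under quantile normalization and -0.065, at the 1.92nd percentile, after loess; Rpl26 (0.018) and Rps29 (0.015) also turned negative under both. The p53 and apoptosis list had a median of -0.011 (40.7th percentile), positive with common median scaling and after loess, with Gadd45a at 0.11 and Ccng1 at 0.40; its 9 second probe sets had a median of -0.41 at the 0.545th percentile. Housekeeping genes had a median of 0.11 (90.8th percentile), with Gapdh at 0.17, Eef1a1 at 0.14 and Rplp0 at 0.01, the last negative under quantile normalization and after loess; the control probe sets of beta-actin gave 0.27 at the 3′ end and 0.39 at the 5′ end. Of the 27 lists scored, 8 lay outside the central 95% of random lists, 6 high and 2 low. By chance 1.35 would if the members of each list varied like randomly drawn genes. Genes of a list are correlated, so more than that can be expected.

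**Figure D3:**
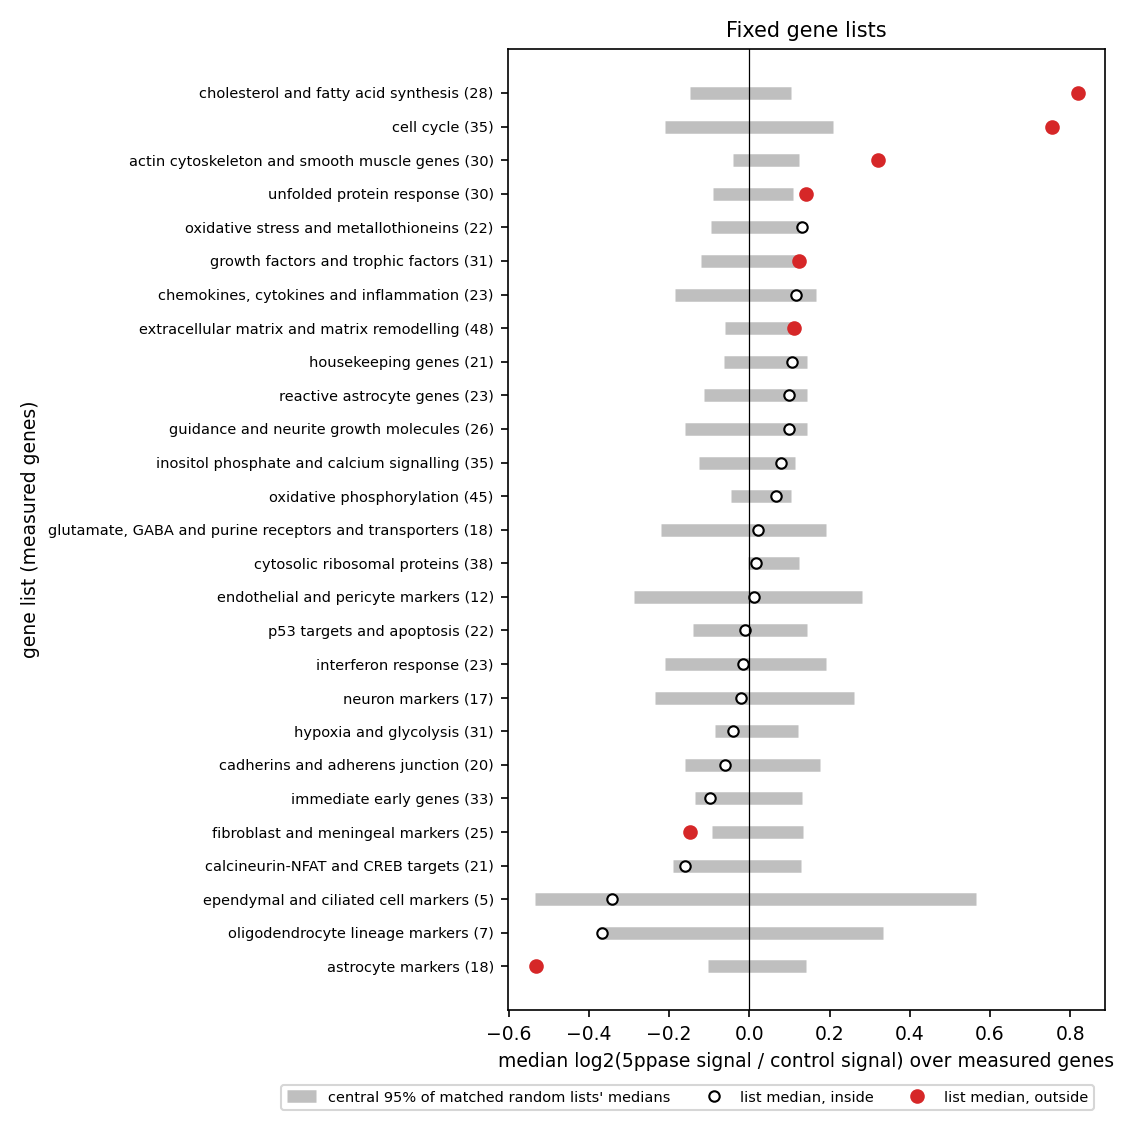
Median log2 ratio of 5ppase over control for each of the 27 scored lists, 1 line per list with its number of measured genes, over a grey bar that spans the central 95% of the medians of 10000 matched random lists; red points lie outside the bar. The cholesterol and fatty acid list lies highest at 0.82 and the astrocyte list lowest at -0.53; medians near 0, such as those of ribosomal, interferon, p53, neuron and receptor genes, turned sign with the scaling.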

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

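All tests of explanations in this part were chosen after the results were seen. Of 10216 probe sets without a gene name here, 2409 met the signal criteria on both arrays, and 47 of them were at least 2-fold higher and 49 at least 2-fold lower in 5ppase, 3.99% together, which drew attention because they lie outside the comparison of named genes. The largest log2 ratios were 2.77 and 2.34 towards 5ppase and -2.66 and -2.45 towards control. The second Inpp5a probe set, which the comparison of brightest probe sets does not use, stood out because it lay at 10.4 on the control array and at 133.6, above the floor, on the 5ppase array.

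Astrocyte markers were lower in 5ppase, with a median log2 ratio of -0.53. Whether the 5ppase culture held more fibroblast or meningeal cells could not be told: that list had a median of -0.15 (0.19th percentile, 25 genes), but -0.063 (7.83rd) with the floor at the 25th percentile and -0.083 (24.8th) with second probe sets, while actin and smooth muscle genes, with a median of 0.32, and Cspg4, at 1.27, were higher. With the loess trend removed the astrocyte median was also -0.53, which argues against a signal-dependent trend as the whole cause. That median was still below all random lists. These lists are matched on signal and share such a trend, so their range adds little to this argument. Whether single probe sets set the result could not be told, since 0 of the markers at least 2-fold lower had a second probe set above the floor on both arrays, although in the 7 markers that had one it pointed the same way as the first (4 lower, 3 higher). A lower astrocyte marker program in cells without calcium signalling, another mix of cells, and an ordinary difference between cultures all stay open, because there is 1 array per group.

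Cholesterol and fatty acid synthesis genes were higher, with a median of 0.82. The median was 0.84 with the loess trend removed and 0.45 over second brightest probe sets (12 genes, 99.95th percentile), so neither a signal-dependent trend nor single probe sets account for the whole pattern. A difference between the 2 cultures other than the construct, such as density, medium or lipid supply, cannot be told apart from an effect of 5ppase with 1 array per group. An effect of lost calcium signalling may therefore be kept only as a hypothesis, one that further pairs of cultures could test.

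Cell cycle genes were higher, with a median of 0.75, many of them close to the floor. With the floor at the 60th percentile, the 9 members with a mean signal above it had a median of 0.56 at the 99.97th percentile. Noise of signals near the floor of 62.0 therefore does not account for the whole pattern. A member of these 9 could still have 1 signal under the raised floor. Second brightest probe sets gave no value, with fewer than 5 measured members. A difference between the 2 cultures other than the construct, for instance in density or in dividing cells of another type, cannot be told apart from an effect of 5ppase with 1 array per group.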

How the results depend on the processing

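Of the alternatives below, those that restrict list members were added after the data were seen. The astrocyte, cholesterol, cell cycle, actin and smooth muscle, and unfolded protein response lists kept their direction and their place outside the range of random lists under every alternative run, except astrocyte (-0.13) and unfolded protein response (-0.074) with second brightest probe sets and cell cycle, which had no value there. Of 313 list values under the alternatives, over all lists, 285 were on the same side of the range as the main value, inside or outside it, and 28 were not. Of the ratios of the 89 named genes over the alternatives, 755 moved by less than the probe set spread of 0.26 and 79 by more. Many gene and list values could hardly move, so these counts overstate stability. The deposited arrays already had a common scale, and averaging probe sets leaves genes with 1 probe set unchanged. The cause of each difference was not tested, except that second brightest probe sets exist for fewer genes and floors and thresholds act on the number of genes counted. Values as deposited and probe sets without _x_at or _s_at moved no list across the range. Signal over background limits the lists whose members lie near the floor, such as cell cycle, with a median control signal of 110. No paired analysis was possible because each group has 1 array.

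The counts of genes at least 2-fold higher and lower were 66 and 56 with the floor at the 60th percentile and the brighter array at the 75th (below, the 60th percentile floor), 134 and 120 with the floor at the 25th, 1111 and 976 with a pseudocount and no filter, 35 and 30 with second probe sets, and 27 and 26 at 3-fold. Genes above the floor in 5ppase only and control only numbered 2 and 3 with the floor at the 25th percentile and 2 and 0 with second probe sets. Of the 241 genes 2-fold apart, 228 were so with a common median, 231 under quantile normalization, 232 after loess, 122 with the 60th percentile floor and 24 with second probe sets. Only 42 genes 2-fold apart had a second probe set compared on both arrays, and all 42 second probe sets pointed the same way.

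Oligodendrocyte markers lay outside the range with a common median (-0.33), quantile normalization (-0.38) and loess (-0.37), calcineurin-NFAT and CREB targets under quantile normalization (-0.18) and ribosomal genes after loess (-0.065). Matrix genes lay inside it under quantile normalization (0.064), loess (0.068), the 60th percentile floor (0.061), the pseudocount (0.108), the mean of probe sets (0.028) and second probe sets (-0.066, reversed), and over members compared on both arrays (0.013, reversed in position). Growth factors lay inside it under quantile normalization (0.071), loess (0.061), the mean of probe sets (-0.015, reversed), second probe sets (-0.0093) and without members above the floor on 1 array only (0.063). Fibroblast markers did so with the 25th percentile floor (-0.063) and second probe sets (-0.083). Adhesion genes lay outside it with the 60th percentile floor (-0.16) and over members compared on both arrays (-0.29), and oxidative stress genes with the mean of probe sets (0.18). With second probe sets, reactive astrocyte (0.55), p53 (-0.41), endothelial (-0.48) and housekeeping genes (0.23) lay outside it. Inside it, medians took the other sign as follows: neuron (0.015) and interferon genes (0.021) with a common median, receptor (-0.014), ribosomal (-0.045) and interferon genes (0.017) under quantile normalization, and interferon genes (0.024) after loess. Neuron (0.22), receptor (-0.17) and interferon genes (0.039) did so with the 25th percentile floor, receptor (-0.16) and endothelial genes (-0.15) with the 60th, and neuron (0.20), receptor (-0.016) and interferon genes (0.081) with the pseudocount. Immediate early (0.065), adhesion (0.14), guidance (-0.043), receptor (-0.30), interferon (0.054) and hypoxia genes (0.021) did so with second probe sets, and receptor (-0.067), endothelial (-0.15) and interferon genes (0.010) over members compared on both arrays. The p53 median, -0.011, was 0.025 with a common median and near 0 but positive after loess and with the 60th percentile floor.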

Other observations

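All tests in this part were chosen after the results were seen. Genes of cell junctions not described above went both ways. The claudin Cldn19 gave 425 in control and 208 in 5ppase (log2 ratio -1.03) and the junction protein Cgnl1 gave 395 and 215 (-0.88). A dim second probe set of Cgnl1 went the other way, at 48.6 and 81.4. The scaffold protein Tjp1 was at -0.36, whereas Esam, an adhesion molecule of endothelial junctions, gave 53.7 and 131. As a group, the 12 measured tight junction genes other than Cldn11, Jam2, Lsr and Ocln lay inside the range of random lists (-0.19). Another 3 genes, for subunits of the NDC80 complex, which ties chromosomes to the mitotic spindle, were higher in 5ppase: Spc24 gave 160.0 and 481 (1.59), Nuf2 gave 74.5 and 225 (1.59) and Spc25 gave 99.7 and 284 (1.51). These genes were chosen after their values were seen.

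Other inositol 5-phosphatases differed in both directions. Inpp5b gave 412 and 619 (log2 ratio 0.59) and Inpp5e gave 231 and 117 (-0.99), while Inpp5k (0.15), Inppl1 (0.066), Synj1 (0.25) and Inpp5f (-0.094) were nearer to 0. These genes, too, were chosen after their values were seen.

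A hypothesis from the lower signals of Cldn11, Jam2, Lsr and Ocln is that tight junction genes as a group may be lower in 5ppase. The other 12 measured tight junction genes had a median log2 ratio of -0.19 at the 9.36th percentile of matched random lists, with 10 lower and 2 higher. That median is inside the central 95% of random lists, from -0.27 to 0.24, so these data do not decide the hypothesis.

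Another hypothesis is that, with Srebf1 lower, the fatty acid genes of the lipid list may differ less between the cultures than its sterol genes. The split used 24 of the 28 measured genes of that list, and no other choice of members was tried. The 16 sterol genes had a median of 1.004 and the 8 fatty acid genes one of 0.60. The difference was 0.40, against an upper end of 0.38 for the central 95% of 10000 random splits of the same genes. The difference passes that limit narrowly, on the genes that raised the question, and with 1 array per group it remains a hypothesis.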
